A study of Homo sapiens with 4 samples.

How the data were processed

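Anti-Flag chromatin immunoprecipitation followed by sequencing was done on Jurkat cells transduced with Flag-HA-tagged BHLHE40 or with an empty vector, in 2 lines each. Lines were grouped by the submitters' sample titles, which also number the replicates. Per the labels the lines were made independently, but p-values computed over peaks or genes measure neither the spread between lines nor that between cultures. Processed peak lists of the 2 BHLHE40 libraries were used. The empty vector libraries were not analysed here, so no comparison between groups and no subtraction of anti-Flag background was made.

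Per the submitters' processing notes, the tools named are Trimmomatic 0.38, Bowtie2 2.2.6, SAMtools and MACS2 2.1.2, and the genome build is GRCh38 (hg38). The control given to the peak caller and its settings are not given in the sources used here. The deposited lists hold peaks called in each replicate separately, in the narrowPeak layout without a header. Each peak has the fold enrichment at its summit, a linear ratio computed by the authors' peak caller. The deposited −log10 p-value and −log10 q-value per peak are also the caller's, and the lowest −log10 q was 1.36 in replicate 1 and 1.44 in replicate 2. The integer score column of the deposited lists was not used. These values are the authors' and were used here to describe, rank and filter peaks. The lists carry no read counts, so depth is unknown, and intervals printed for shares cover counting of peaks or genes alone. A library with more reads or a lower background lists more weak peaks, which can move the number of peaks and the overlap.

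Shared peaks were peaks of both replicates overlapping by at least 1 bp, merged into 1 region, with the highest fold of each replicate and the summit of the replicate with the higher fold. Overlap was tested against 1000 random placements on the same chromosome, between its first and last annotated gene, with assembly gaps not left out. Differences in median log2 fold and correlations were tested with 100000 permutations, two-sided. Gene positions came from the RefSeq annotation of GRCh38.p14, with 19974 protein-coding genes on 22 autosomes and X. Shifting all summits by 5 to 100 kb took the share near gene ends from 34.3% to between 5.12 and 6.55%, a check that files and gene table use the same build.

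The plan called for transcription start sites, exons and E-box sequences. The gene table used here has gene spans without strand or exons, and no genome sequence was used. A gene was therefore counted when a shared summit lay within 1 kb of either end of its span, inside or outside, and the places were gene end, inside a gene and outside genes. Alternative starts inside a span are missed, and neighbouring genes can share a peak.

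Gene lists, tests and the rule for named genes were set before the data were examined. The 16 lists held 407 distinct genes, with 1 listed symbol absent from the protein-coding table. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment and a threshold of 0.05. Named are the 15 genes with the highest lower fold of both replicates, the members with a peak of the circadian, cytokine, RNA decay and E-box factor lists, at most 4 members of each other list, the nearest peaks of CSF2, ZC3H12D, IL10 and BHLHE40, and the 5 strongest shared peaks over 10 kb from a gene end. Some genes that this rule takes are not reported here. Other names were chosen after their values were seen and are marked so, or belong to alternatives with a 5 kb window or to the gene nearest to a named peak. Shares of shared peaks per chromosome were compared with shares of protein-coding genes by Fisher's exact test with the same adjustment.

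Alternatives were a reciprocal overlap of 50%, summits within 100 bp, a −log10 q of at least 5, a fold of at least 5, equal numbers of peaks, windows of 500 bp and 5 kb, the nearest gene within 50 kb, and each replicate alone. In simulated data, 499 of 500 simulated shared sites and 100.0% of 200 seeded genes among 19974 were recovered. Shared sites were simulated at nearly the same position in both lists, and those of seeded genes at a gene end. Recovery was thus largely set by the simulation, which checks the code and not the power in the real lists. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.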

Results

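The data came from Jurkat cells, an established human T cell leukaemia line, transduced with a lentivirus that expresses BHLHE40 tagged with Flag-HA. BHLHE40 is a basic helix-loop-helix transcription factor that binds E-box DNA and acts in the circadian clock and in T cell cytokine control. Chromatin was immunoprecipitated with an anti-Flag antibody in 2 BHLHE40 lines, described as independent and called replicates 1 and 2, and in 2 lines with the empty vector, for which no peaks were analysed here. The deposited peak lists held 3100 peaks in replicate 1 and 3444 in replicate 2, with median widths of 336 and 327 bp. Median fold enrichment was 6.28 and 6.24, the highest was 45.8 and 64.5, and 93 and 132 peaks reached a fold of 20. The lists give no read counts, so the sequencing depth of each library is unknown. No empty vector value is printed beside the values below, and it is not known whether the caller's folds already take that background into account.

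The first question was which sites were bound in both lines. The strongest shared peaks included a site inside KCNAB2, a potassium channel subunit gene, on chromosome 1 from 6025960 to 6026727 (GRCh38), with folds of 45.8 and 64.5 in replicates 1 and 2. In all, 2531 peaks of replicate 1 (81.6%, Wilson 95% interval 80.2 to 83.0%) overlapped a peak of replicate 2 by at least 1 bp. In the other direction, 2529 peaks of replicate 2 overlapped (73.4%, 71.9 to 74.9%), and the overlapping peaks merged into 2518 shared peaks. Random placement on the same chromosomes gave a mean of 3.28 and 3.29 overlapping peaks and never more than 10, with a one-sided permutation p = 0.000999 for both, the smallest that 1000 placements can give. The overlap rose with strength, from 57.8% of the peaks below the lower quartile of fold in replicate 1 to 99.6% of those above the upper quartile, and from 42.2% to 99.3% in replicate 2.

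Sites strong in one line were strong in the other. Across the 2518 shared peaks, which are not independent replicates, Spearman's rho was 0.741 and Pearson's r of log2 fold was 0.816, with a permutation p = 1e-05 for each, the smallest that 100000 pairings can give. The log2 ratio of replicate 2 to replicate 1 had a median of 0.08 and an SD of 0.41, and 84.0% of shared peaks differed by less than 1.5-fold. The peak at RAB7A had folds of 34.2 and 35.0 and that at LAMP1 32.6 and 30.5, whereas the peak at CRY1 had 10.9 and 19.3 and that at HES4 13.4 and 5.64. Peaks listed in a single replicate were weaker, with a median fold of 4.93 against 6.95 for shared peaks in replicate 1 and 4.82 against 7.36 in replicate 2 (two-sided permutation p = 1e-05 each, the smallest possible). Of the 569 and 915 unshared peaks, 14 and 27 exceeded the shared median.

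**Figure D1:**
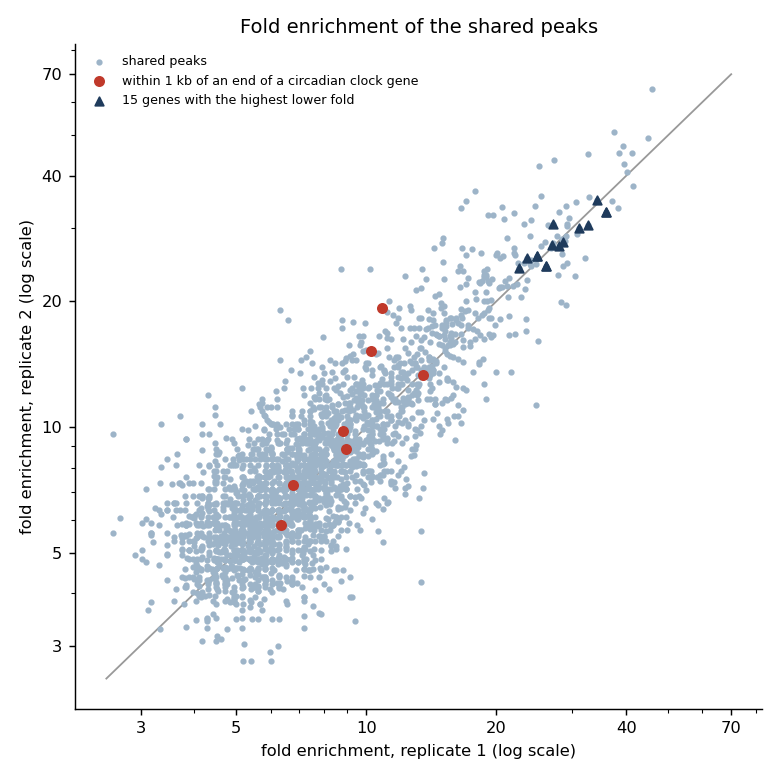
Fold enrichment of the 2518 shared peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with the line of equal values. Red points are the peaks within 1 kb of an end of 7 circadian clock genes and triangles those of the 15 genes with the highest lower fold, which lie at 22.5 or higher in both replicates.

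The second question was where in the genome the shared peaks lay. Summits within 1 kb of an end of a protein-coding gene made up 864 of the 2518 (34.3%, Wilson 95% interval 32.5 to 36.2%), against 2.94% of random positions on the same chromosomes, an 11.7-fold difference (two-sided permutation p = 0.002, the smallest possible). The difference was 17.1-fold within 500 bp and 4.11-fold within 5 kb. Against positions shifted by 10 to 100 kb from each summit, a comparison chosen after seeing the data, 5.92% were expected and the difference was 5.80-fold. A further 1105 summits (43.9%) lay inside genes over 1 kb from their ends, and 549 (21.8%) outside genes against 55.2% of random positions. Random positions were not kept out of assembly gaps, where no peak can be called, which can raise the random share outside genes and lower that at gene ends. Of locally shifted positions 36.3% lay outside genes. The share inside genes exceeded the random 41.9% with a permutation p = 0.044, which rose to 0.0939 with a −log10 q of at least 5 and to 0.148 in replicate 2 alone, and was 0.00799 in replicate 1 alone. It was below the 57.7% of locally shifted positions, and with a 5 kb window it was below random (33.0% against 36.4%, permutation p = 0.002), so no direction is given for it. The median of the lower fold varied little with place, at 6.50 at gene ends, 6.12 inside genes and 6.25 outside them. The upper quartiles were 8.61, 8.61 and 9.04. No test was made, and these values do not describe the strongest peaks. The gene table used has no strand, so the transcribed start and the far end of a gene were counted alike.

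**Figure D2:**
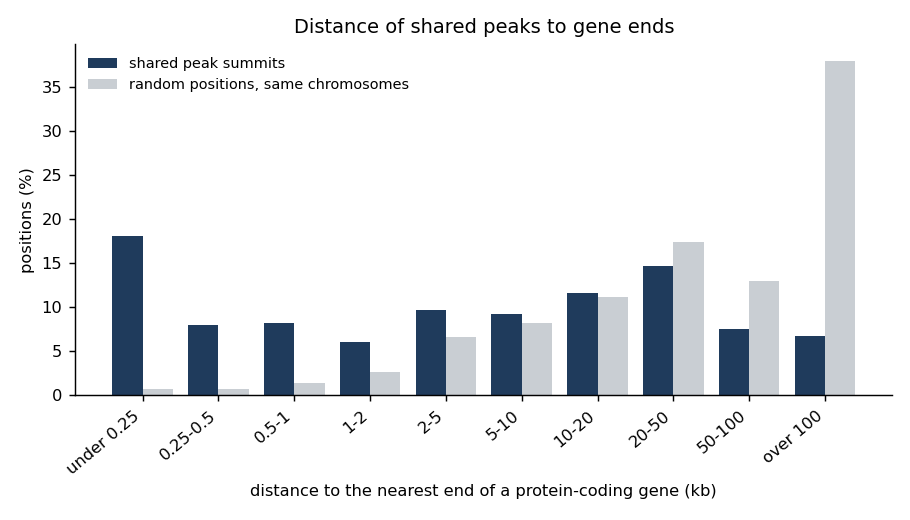
Share of the 2518 shared peak summits (dark bars) and of random positions on the same chromosomes (grey bars) by distance in kb to the nearest end of a protein-coding gene. Of the summits, 18.1% lay under 0.25 kb from an end, against 0.766% of random positions.

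Of 19974 protein-coding genes, 1008 (5.05%) had a shared peak within 1 kb of an end. The 15 with the highest lower fold were led by RAB7A, a small GTPase of late endosomes, with folds of 34.2 and 35.0 at a peak on chromosome 3 from 128725773 to 128726281, 108 bp outside the gene. ADIRF and the neighbouring LOC124902474 shared a peak of 35.9 and 32.7. LAMP1, a lysosomal membrane protein, followed with 32.6 and 30.5, on chromosome 13 from 113296745 to 113297217. MZB1, an endoplasmic reticulum protein, had 31.0 and 29.9, GTF2A1, a subunit of the general transcription factor TFIIA, had 28.6 and 27.7, and SURF6, a nucleolar protein, had 27.9 and 27.2. YDJC had 27.0 and 30.7, and INSIG1, which holds back sterol synthesis, had 26.9 and 27.3. ERP29 and TMEM116 shared a peak of 24.8 and 25.7, and ABHD17A and KLF16 shared a peak of 26.1 and 24.4. ZFAT had 23.6 and 25.4, and ANKRD12 had 22.5 and 24.0.

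The strongest shared peaks over 10 kb from any gene end lay mostly inside long genes. Besides KCNAB2, they were inside ZNRF1 (folds of 41.3 and 45.4, chromosome 16 from 75075080 to 75075754), SEPTIN9 (40.1 and 40.8, chromosome 17 from 77445042 to 77445977) and ZFYVE28 (39.5 and 42.7, chromosome 4 from 2290740 to 2291442). The fifth, with 39.3 and 47.2, lay outside genes on chromosome 6 from 22062737 to 22063529, where the nearest protein-coding gene was PRL at 224 kb. In all, 1025 shared peaks (40.7%) were over 10 kb from any gene end.

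The third question was which groups of genes carried shared peaks. Of the circadian clock genes, 7 of 23 (30.4%, Wilson 95% interval 15.6 to 50.9%) had one within 1 kb of an end, against 5.02% of the other protein-coding genes (odds ratio 8.28, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000523 over 16 lists). They were the repressor genes NR1D1 (folds of 13.5 and 13.3), CRY1 (10.9 and 19.3), NR1D2 (8.95 and 8.88), CRY2 (8.81 and 9.78), PER1 (6.35 and 5.84) and BHLHE40 (6.77 and 7.26), and the activator DBP (10.2 and 15.2). The NR1D1 peak lay on chromosome 17 from 40100491 to 40101173, 132 bp from the gene. The NR1D2 summit lay 959 bp from an end of NR1D2 but 317 bp from an end of NKIRAS1. A stronger peak, of 37.5 and 51.0, lay 4111 bp from PER1 on chromosome 17 from 8156158 to 8156992, with VAMP2 nearest at 2632 bp. With BHLHE40 left out after seeing the data, 6 of 22 clock genes had a peak (adjusted exact p = 0.00321).

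Lysosome and autophagy genes had the highest share within 1 kb of an end, 9 of 28 (32.1%, odds ratio 8.98, adjusted p = 9.5e-05 by Fisher's exact test). Beside LAMP1 they included ATP6V1H, a subunit of the proton pump that acidifies lysosomes, with folds of 16.0 and 10.6, RRAGC, a GTPase of nutrient sensing, with 10.5 and 11.9, and FLCN with 12.7 and 8.88. In the glycolysis and hypoxia list 8 of 28 genes had a peak (28.6%, odds ratio 7.58, adjusted exact p = 0.000412), among them the glycolytic enzyme genes GPI (16.2 and 18.1), PFKP (11.4 and 12.7) and GAPDH (11.6 and 9.26), and HIF1A (8.96 and 14.6), the oxygen-regulated transcription factor.

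T cell identity and receptor signalling genes had 6 of 27 (22.2%, odds ratio 5.40, adjusted exact p = 0.00773). With ends within 5 kb they had 10 of 27 against 10 of 28 lysosome genes. With the nearest gene within 50 kb the counts were 12 of 27 and 9 of 28. CD28, a costimulatory receptor, had folds of 14.8 and 9.62, the lineage transcription factor BCL11B 8.95 and 9.90, the T cell receptor component CD3E 7.11 and 9.39, and the receptor-proximal kinase ZAP70 6.28 and 5.45. The CD3E summit lay 698 bp outside its span, beyond the end with the higher coordinate, which may or may not be its start. Ribosome biogenesis genes had 5 of 22 (22.7%, odds ratio 5.56, adjusted exact p = 0.0133), namely NOP14, NCL, NOP56, POLR3G and RRP9, with folds from 8.60 and 10.7 at NOP14 to 4.72 and 5.03 at RRP9. Sterol and fatty acid synthesis genes had 5 of 24 (20.8%, odds ratio 4.97, adjusted exact p = 0.0165), among them INSIG1, SCD and LSS. RRP9 was named after its values were seen. The sterol list was lost with ends within 5 kb (adjusted exact p = 0.0686) and with a −log10 q of at least 5 (adjusted p = 0.0591).

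The 6 lists above were set against all other protein-coding genes, which include genes that a T cell does not use. Of the 407 distinct genes on the 16 lists, 63 (15.5%) had a shared peak. Set against the genes of the other 15 lists, a background chosen after seeing the data, 0 lists passed by Fisher's exact test, 1 had an unadjusted p under 0.05 (lysosome, 0.0251), and the smallest adjusted p was 0.320. That background was not matched for expression. It holds genes of other tissues and, for each of the 6 lists, the other passing lists, which makes a pass less likely. It therefore cannot show whether use in T cells accounts for the 6 lists.

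**Figure D3:**
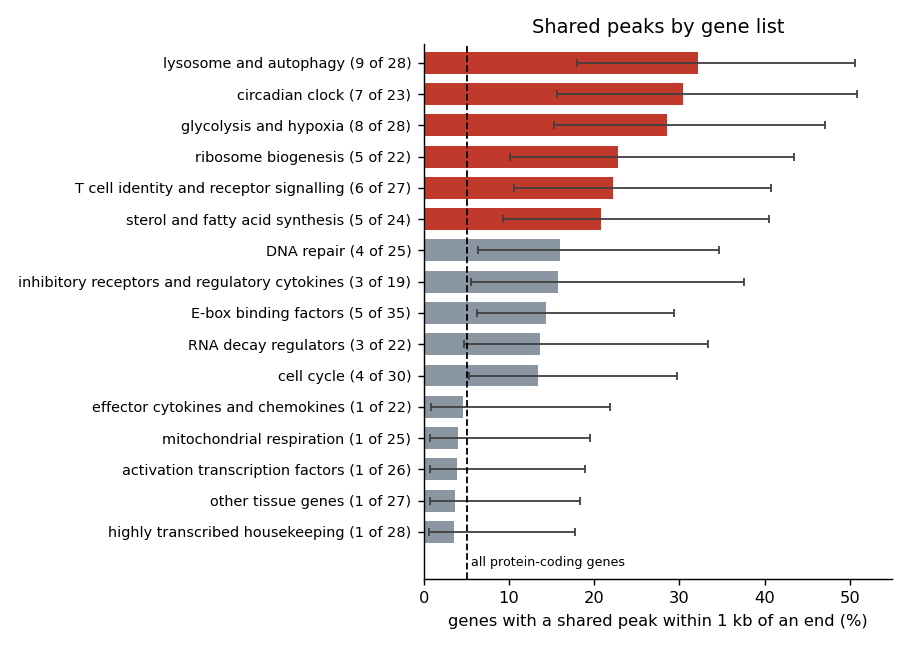
Percent of the genes of each list with a shared peak within 1 kb of an end (x axis), with Wilson 95% intervals, and the share of all 19974 protein-coding genes (5.05%) as a dashed line. Red bars are the 6 lists past an adjusted p of 0.05 against all other protein-coding genes.

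Genes of effector cytokines and chemokines were not among the lists that passed, with 1 of 22 (4.55%, Wilson 95% interval 0.807 to 21.8%, adjusted exact p = 1.0). That gene was IL5, through a peak with folds of 17.0 and 22.1 on chromosome 5 from 132556714 to 132557395. Its summit lay 128 bp from an end of the annotated IL5 span and 34 bp from an end of RAD50, a DNA repair gene. The IL5 span used runs from 132541445 to 132556815, and starts inside a span are missed. The peak therefore cannot be assigned to IL5 rather than RAD50, and the only hit of this list is uncertain. CSF2, which encodes the cytokine GM-CSF, had no peak of either replicate closer than 114 kb, where replicate 1 alone listed a peak of 6.05. The nearest shared peak was 390 kb away with 5.83 and 4.21. In the same cluster, chosen for display after the values were seen, a shared peak of 17.9 and 36.8 lay 559 bp from KIF3A and 5575 bp from IL4. IL10, an anti-inflammatory cytokine gene, had a peak 1027 bp away in replicate 2 alone, with a fold of 4.94, and the nearest shared peak was 204 kb away.

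**Figure D4:**
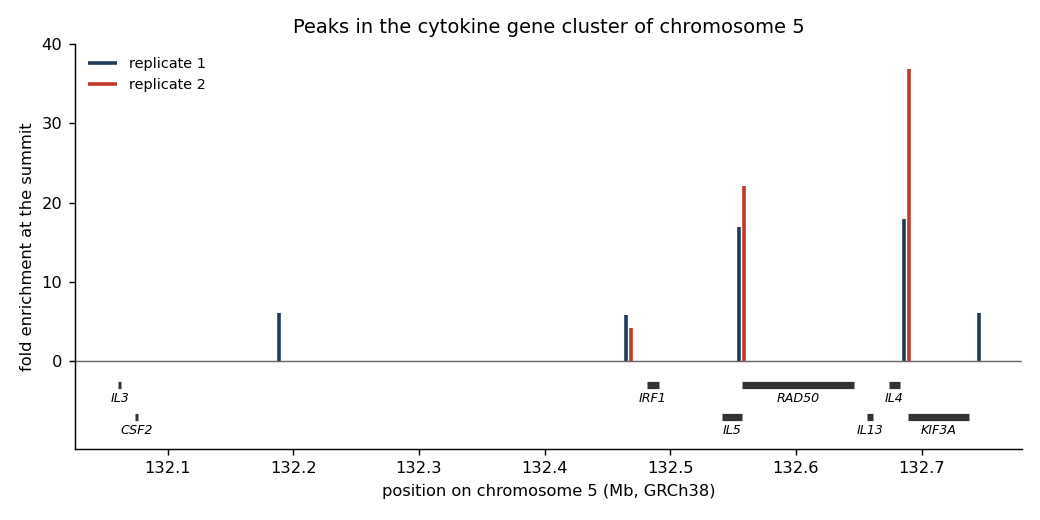
Peaks in the cytokine gene cluster of chromosome 5, with position in Mb (GRCh38) on the x axis and fold enrichment of replicates 1 and 2 on the y axis as vertical lines, drawn slightly apart. Gene spans are drawn below the axis, and the highest lines are the peaks beside KIF3A (17.9 and 36.8) and between IL5 and RAD50 (17.0 and 22.1).

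RNA decay regulators had 3 of 22 (13.6%, odds ratio 2.98, adjusted exact p = 0.141). ZC3H12D, a relative of the RNase Regnase-1, had folds of 9.97 and 10.7 at a peak on chromosome 6 from 149484742 to 149485201, with summits 8 and 22 bp from the gene end. CNOT3, a subunit of the deadenylase complex, had 9.59 and 11.4, and HNRNPD, which binds AU-rich RNA, had 4.17 and 8.81. The CNOT3 summit lay 627 bp from an end of CNOT3 but 107 bp from an end of LENG1. A stronger peak, of 38.4 and 33.4, lay 4289 bp from ZFP36, with MED29 nearest at 1917 bp, and with ends within 5 kb the list passed (odds ratio 4.32, adjusted exact p = 0.0145), but not with the nearest gene within 50 kb (odds ratio 2.17, adjusted exact p = 0.208). E-box binding factors had 5 of 35 (14.3%, odds ratio 3.15, adjusted exact p = 0.0684), with MAX at 9.89 and 8.12, BHLHE40, HES4, HES6 at 5.61 and 6.85, and MLX at 4.02 and 3.84. Leaving out BHLHE40 after seeing the data gave 4 of 34 E-box binding factors (odds ratio 2.52, adjusted exact p = 0.140). With BHLHE40 counted, the list passed with ends within 5 kb (8 of 35, adjusted exact p = 0.0145) and with the nearest gene within 50 kb (12 of 35, odds ratio 5.10, adjusted exact p = 0.000239).

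The other lists did not pass within 1 kb in both replicates, though 4 of them did under other settings. The list of inhibitory receptors and regulatory cytokines, which also held other regulators such as TNFAIP3, had 3 of 19 (adjusted exact p = 0.109). They were LAG3 with 12.3 and 11.4, IL10RA with 6.72 and 7.28 and TNFAIP3 with 6.31 and 6.30. The LAG3 summit lay 438 bp outside its span, beyond the end with the higher coordinate. Without strand, it is not known here whether that end is its start. DNA repair had 4 of 25, among them RAD50, PARP1 and NBN (adjusted exact p = 0.0700), and cell cycle 4 of 30, namely CDK4, MCM2, MCM6 and CDK6 (adjusted exact p = 0.109). A single gene had a peak among activation transcription factors (FOSL2, 1 of 26), mitochondrial respiration (1 of 25), highly transcribed housekeeping genes (HNRNPK, 1 of 28) and genes of other tissues (KRT1, 1 of 27), each with an adjusted exact p = 1.0. Inhibitory receptors passed with the nearest gene within 50 kb (adjusted exact p = 0.0139) and in replicate 1 alone (0.0485), DNA repair in replicate 1 alone (adjusted exact p = 0.0343), cell cycle with ends within 5 kb (adjusted exact p = 0.0165), and activation transcription factors with the nearest gene within 50 kb (odds ratio 3.60, adjusted exact p = 0.0162). Against the housekeeping list, the circadian clock list had an unadjusted Fisher's exact p = 0.0164, or 0.123 adjusted over 15 lists, and in replicate 1 alone the unadjusted exact p was 0.0610.

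Shared peaks were spread unevenly over chromosomes relative to their protein-coding genes. Chromosome X held 16 shared peaks, 0.635% against 4.25% of genes (ratio 0.15, Fisher's exact test, Benjamini-Hochberg adjusted p = 6.3e-25 over 23 chromosomes). Chromosomes 9 (ratio 1.43, adjusted exact p = 0.00163), 17 (1.30, 0.00482) and 2 (1.23, 0.0345) held more than their share, and chromosome 1 less (0.82, 0.0184). With chromosome length as the expectation, chosen after seeing the data, 13 chromosomes passed, and X stayed the lowest at a ratio of 0.12, whereas chromosomes 1 and 2 did not pass. By length chromosome 17 had a ratio of 2.78, and chromosome 19 had 3.22 (adjusted exact p = 7e-31), the highest of all, after 0.86 by genes. Jurkat cells are not diploid everywhere, and copy number can change the number of peaks called. Copy number was not measured here, so these ratios, that of X included, are not read as a binding preference.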

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

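The background of other lists, the local shifts, chromosome length, the divergent transcripts, the lists without BHLHE40 and other settings for circadian against housekeeping genes were chosen after seeing the data. Of 158 alternatives, 131 kept the direction and the side of the threshold or, for counts, stayed within 1.5 times the main value. Overlap, concordance, the excess of shared peaks at gene ends and the weakness of unshared peaks held their direction and threshold under each alternative run, though the excess at gene ends ranged from 4.11-fold within 5 kb to 17.1-fold within 500 bp. The count of gene lists past the threshold, 6, ranged from 6 to 8 with each replicate alone, was 8 with ends within 5 kb, 9 with the nearest gene within 50 kb and 5 with a −log10 q of at least 5, and fell to 0 with the genes of the other lists as background. With chromosome length as the expectation, 13 chromosomes passed in place of 5. Odds ratios changed side of 1 in 9 alternatives, and the cause was not tested. With the nearest gene within 50 kb, activation transcription factors went from 0.75 to 3.60, past the threshold, effector cytokines from 0.90 to 1.54, and housekeeping genes from 0.70 to 1.17. Housekeeping genes had 1.38 with ends within 5 kb and 0.49 to 1.20 with each replicate alone, and mitochondrial respiration 0.65 to 1.16. With the other lists as background, RNA decay had 0.86, cell cycle 0.83 and E-box factors 0.90, none past the threshold. Among 112 alternatives for single lists 8 were weaker and 7 stronger. The stronger ones were E-box factors with both wider windows, RNA decay and cell cycle at 5 kb, inhibitory receptors at 50 kb and in replicate 1 alone, and DNA repair in replicate 1 alone. The weaker ones were the 6 lists with the other lists as background and the sterol list with a 5 kb window or a −log10 q of at least 5. No paired analysis was possible because the empty vector libraries were not analysed here. Planned steps that need a genome sequence or exons were not run, namely the E-box share at summits, the ranking of hexamers, enrichment with and without an E-box, the repeat filter, backgrounds of genes with an E-box or a CpG-rich end, exon and intron classes, and non-N bases as the chromosome expectation. Without read counts, it is not known how far depth limits the unshared peaks.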

Other observations

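The counts by gene span, symbol family and gene class in the next sentences and the test on single gene ends were chosen after gene hits had been seen, and the test on divergent transcripts after those hits but before its own result. Several genes held many shared peaks within their span, which the gene-end counts do not show. HDAC4, a histone deacetylase gene of 353 kb, held 9, CCDC88C and GSE1 held 6 each, and IGF1R and KLHDC4 held 5 each, with no test against gene length. Of 96 symbol families, 1 passed, the olfactory receptor genes, with fewer peaks than other genes (adjusted p = 6e-06 by Fisher's exact test, and 8 families had an unadjusted p under 0.05). Long non-coding RNA genes had a shared peak at an end in 1.93% of cases and pseudogenes in 0.125%, against 5.05% of protein-coding genes, with no correction for gene length. Shared peaks exceeded those listed in 1 replicate only by at least 0.49 in median log2 fold in both replicates.

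The gathering of shared peaks at gene ends was set against an explanation in which strongly transcribed genes collect anti-Flag signal whatever the tagged protein. That explanation needs housekeeping genes to match the circadian clock genes, and they had a peak in 3.57% against 30.4% (Fisher's exact p = 0.0164, unadjusted). It also needs tRNA genes, which are strongly transcribed, to exceed protein-coding genes, and 2.26% of them had a peak against 5.05% (exact p = 0.00544), but against single gene ends, a target as wide as a short gene, it was 2.26% against 2.58% (exact p = 0.879), which decides nothing. The housekeeping value counts only thinly against it as the whole cause, since the comparison rests on 1 of 28 and 7 of 23 genes, its p was 0.123 adjusted over 15 lists and 0.0610 in replicate 1 alone, and GAPDH, ENO1 and LDHA, strongly transcribed glycolysis genes of which the last 2 were named after their values were seen, did have peaks. Part of the signal may still be background, since the empty vector libraries were not analysed here, and no biological explanation was tested.

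Because the gene table has no strand, a hypothesis that the peaks lie at transcribed starts was tested on genes with an annotated divergent transcript, which marks the start. Among genes of this kind with a shared peak at a single end, 54 had it at the end nearer the divergent transcript and 2 at the far end (96.4%, exact binomial p = 4.4e-14). The values go with peaks lying at starts for these 54 and 2 genes only, out of 560 genes chosen by having such a partner. They do not cover the other genes with a gene-end peak. The share was 89.1% with a 5 kb window.

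The transduced vector could leave its own traces at BHLHE40 and EEF1A1. Copies of the transduced BHLHE40 coding sequence would give summits in the gene body, and each replicate had 1, over 1 kb from both ends, with folds of 6.46 and 5.68, so that body peak may come from the vector, while the peak 949 bp outside the gene would not be covered by coding sequence. Copies of the EF1a promoter would give a peak within 1 kb of EEF1A1, and the nearest summit of either replicate was 53900 bp away. This cannot decide the matter, since the promoter of the vector is not given in the sources used here. The control given to the peak caller is not given either, and a control with the same copies would cancel such a peak.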
